A study of Mus musculus with 9 samples.

How the data were processed

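RNA of mouse NIH 3T3 fibroblasts, an established line, was measured on 9 Affymetrix arrays. The arrays fall into 3 groups of 3: control, cytochalasin D, and latrunculin B with cytochalasin D. Per the labels' protocols, cells were serum-starved, and every group received cycloheximide, a blocker of translation, at 3 µg/ml for 2 h. Cytochalasin D was given at 2 µM and latrunculin B at 5 µM, each for 90 min. The sample titles of the third group name latrunculin B alone, whereas its agent label and the series design name both drugs. The agent label was followed, and the group is called the double-drug group. The series design states that the 3 arrays of a condition are independent biological replicates, and their labels number them 1, 3 and 7.

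The deposited values are intensities on a linear scale, 1 per probe set and array, normalized by the authors. The submitters' processing notes name MAS5 and GCRMA, without versions and without saying which of them made these values. The scale was read from the values: the median intensity per array lay between 7.57 and 7.84. No value was missing among the 45101 probe sets. Of the 36 pairs of arrays, 0 were identical, and at most 5.06% of the values of a pair were equal.

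Gene symbols came from the platform annotation deposited with the array type, updated through gene identifiers with a reference gene table of assembly GRCm38.p6, which was used for names only. Of the probe sets, 34958 carried 1 symbol and 932 several in that annotation, some of the 64 control probe sets among them. Apart from control probe sets, 9160 carried none. No gene was named from a probe set with several symbols, and no genome positions are given, because no build goes with the deposited values.

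Intensities were changed to log2(intensity + 16), which makes the changes of dim probe sets smaller than they would be without the added 16. A probe set was tested if it lay above the 40th percentile of its own array on at least 3 arrays. This left 27010 probe sets, 22822 with 1 symbol, 674 with several and 3514 with none, covering 12651 genes. Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with its default prior), with 1 coefficient per group and all 9 arrays in the fit. The 3 contrasts were cytochalasin D against control, the double-drug group against control, and cytochalasin D against the double-drug group. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested in each contrast, and a probe set was called at an adjusted p under 0.05. Probe sets called in both contrasts that involve cytochalasin D, with the same sign, form the switch set, named after the series title. Values per group are means of intensities with their standard deviations (SD) over 3 arrays, log2 changes carry standard errors (SE) from limma, and the number of arrays limits the precision of all of them.

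There were 27 gene lists, fixed before the data were examined, as were the main model, the rule for named genes and the alternatives, apart from those named below as added. The lists hold targets of myocardin-related transcription factors and serum response factor (MRTF-SRF), genes followed up by the study group, immediate-early genes, actin and actin-turnover genes, focal adhesion genes, smooth muscle contractile genes, YAP/TAZ-TEAD targets, NF-kappaB targets, feedback inhibitors of receptor and ERK signalling, EGF family ligands, extracellular matrix genes, and TGF-beta and BMP response genes. Further lists hold p53 targets, G2/M genes, G1/S and DNA replication genes, stress response genes (unfolded protein and integrated stress response), heat shock genes, cholesterol synthesis genes, circadian clock genes, and tubulins and microtubule proteins. Results of 1 further list are not given. The last 6 lists hold markers of fibroblasts, of macrophages and leukocytes, and of epithelial, endothelial, adipocyte and skeletal muscle cells. Together they hold 525 memberships, of which 498 had a named probe set and 431 a tested one. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01, on the tested probe set with the highest mean of each gene. The 81 tests were adjusted together, and the same test with the correlation estimated from the data was run as an alternative. Of the 32 list tests called, 15 held with the estimated correlation. Members called are counted over all probe sets tested and, beside that, adjusted over the list alone.

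Named genes follow a rule: in each contrast and in the switch set, the 10 genes with the largest rise and the 10 with the largest fall among called probe sets whose group values did not overlap. To these come 15 fixed genes and, for each list, up to 4 members with the smallest adjusted p. The probe set of a gene with the highest mean over the 9 arrays was used, and probe sets with no symbol, several symbols or a clone name were passed over. The rule passed over 1 rise and 2 falls of cytochalasin D against control, 2 rises of cytochalasin D against the double-drug group, and 2 rises of the switch set. Fewer than 10 falls were available in the contrasts with the double-drug group. Genes named outside the rule are marked as chosen after their values were seen.

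Whether the replicate numbers pair the arrays was checked by correlating, across probe sets, the deviations of same-numbered arrays from their group means. For the double-drug group against control the correlations were 0.834, 0.413 and 0.663 for numbers 1, 3 and 7. For cytochalasin D against the double-drug group they were 0.726, 0.411 and 0.756. All 6 lay over 0.1, so the numbers pair the arrays in these 2 contrasts by the data. For cytochalasin D against control the correlations were 0.71, 0.076 and 0.653, although each array matched its own number best. The numbers may pair this contrast too. Its main results are given without them, with the count of the paired fit beside. The labels do not say what a number marks. Adjusted p with the pairs are from a limma fit with the replicate number as a further factor, and are given where they change a call or move a count by more than 1.5 times.

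Alternatives to the main model were quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, eBayes with trend and robust estimation, the replicate number as a factor, a fit on the 6 arrays compared, an added minimum change of 2-fold, 1 probe set per gene, pseudocounts of 1 and 64, and each array left out in turn. For the lists, the estimated correlation and the mean over the probe sets of a gene were tried as well. Leaving out all 3 arrays of a replicate number was added after seeing the data.

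The model was tested on simulated data with 200 probe sets changed in the cytochalasin D arrays among 27010, with 50 of each size. For cytochalasin D against control it recovered 54% of the changes of log2 0.5, 76% of those of 1, 100% of those of 2 and 98% of those of 3. In that contrast 8 of 172 calls fell on unchanged probe sets, in cytochalasin D against the double-drug group 14 of 177, and in the double-drug group against control 0 were called. A list of circadian clock genes shifted by 0.5 was called, and 0 of the 26 other lists were. The simulated noise was independent between probe sets and held no structure by replicate number. False list calls from correlated genes could therefore hardly arise, so the list result does not test the preset correlation. In the data the estimated correlation was 0.218 for MRTF-SRF targets and 0.307 for immediate-early genes. What comparisons give when they share arrays was simulated 20 times with no effect. Single values were compared with exact permutation tests, and sets of genes with permutation tests of 100000 resamples. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.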

Results

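The data are 9 expression arrays of NIH 3T3 fibroblasts, 3 each from control cultures, cultures given cytochalasin D for 90 min, and cultures given latrunculin B together with cytochalasin D, all of them under cycloheximide. Both drugs act on actin. Cytochalasin D caps filaments and releases the coactivator MRTF from monomeric actin (G-actin), whereas latrunculin B binds G-actin and keeps MRTF bound to it. MRTF is a coactivator of serum response factor (SRF), which itself is held at many genes of the actin cytoskeleton. The series title speaks of genes regulated by a G-actin switch, and the 3 contrasts ask which transcripts differ between the states. Median intensities of the arrays ran from 7.57 to 7.84, and 27010 probe sets were tested.

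The first contrast asks what cytochalasin D changed within 90 min without new protein synthesis. Acta1, skeletal muscle alpha-actin, had an intensity of 19.2 ± 1.07 in controls and 1168 ± 479 with cytochalasin D (SD, n = 3), a log2 change of 5.00 (SE 0.30, adjusted p = 0.00115), and binding of transcripts of its relative Acta2 to this probe set was not excluded. Myl9, the regulatory light chain of smooth muscle and non-muscle myosin, went from 126 ± 56.5 to 1568 ± 272 (SD, n = 3), a log2 change of 3.56. Tagln, the actin-binding protein transgelin, went from 483 ± 241 to 4408 ± 317 (SD, n = 3), a log2 change of 3.28 (adjusted p = 0.00868). Srf, which encodes SRF itself, rose from 187 ± 30.9 to 1475 ± 311 (SD, n = 3), a log2 change of 2.87 (adjusted p = 0.00191). Other genes among the 10 largest rises were Nppb, a natriuretic peptide (3.43), Fam126b (2.88), Dusp5, a nuclear phosphatase of ERK (2.86), Palld, the stress fibre protein palladin (2.81), Lurap1l (2.71) and Pkp2, the desmosomal protein plakophilin 2 (2.66). Nppb lost its call without control replicate 7 (adjusted p = 0.0586) or cytochalasin D replicate 3 (adjusted p = 0.0505). Where a gene had several probe sets they did not always share the call: 2 of 3 rose for Palld, Lurap1l, Pkp2 and Ier5, 2 of 4 for Ccn1 and Itga5, 1 of 2 for Vcl and Btg2, 4 of 5 for Lima1 and 1 of 3 for Atf4, and none fell. Likewise 1 of 3 fell for Dusp7 and 1 of 2 for Hspe1 and Socs5.

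In this contrast 423 probe sets were called, 309 higher and 114 lower with cytochalasin D, for 220 and 93 genes. At least a 2-fold change was seen in 169 of the higher and 14 of the lower ones. In all 423, the 3 cytochalasin D values lay on 1 side of the 3 control values; among all probe sets tested 11.5% were parted in this way, where chance gives 10%. The count was 235 without control replicate 3, 242 without control replicate 7, 227 without cytochalasin D replicate 3 and 276 without double-drug replicate 3. With the replicate number as a factor it was 1044 (626 higher, 418 lower), and in a fit on the 6 arrays compared 159 (136 higher, 23 lower).

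The plot of 9 genes across the arrays shows how far the groups were parted.

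**Figure D1:**
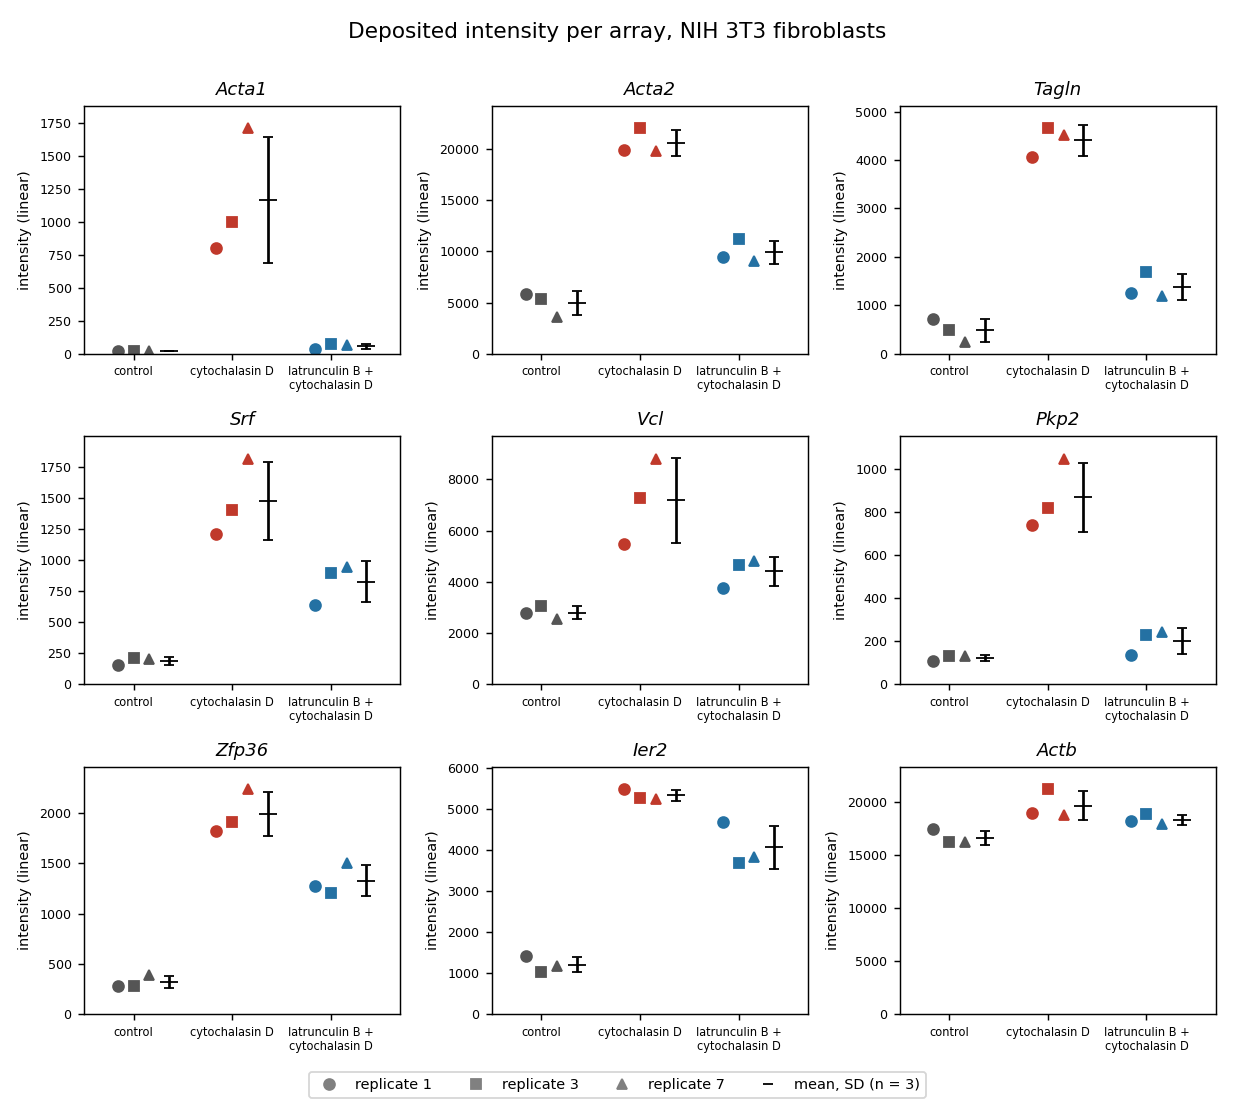
Intensity (linear scale, y axis) of 9 genes on each array (x axis: control, cytochalasin D, latrunculin B with cytochalasin D; marker shape: replicate number; bars: mean and SD of 3 arrays). Acta1 averaged 19.2 in controls, 1168 with cytochalasin D and 56.0 in the double-drug group, whereas Zfp36 averaged 320, 1993 and 1327; the changes of Actb did not pass the test in any contrast.

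MRTF-SRF targets rose as a group. Of 39 tested members 26 rose, 0 fell and 13 were not called (35 rose adjusted over the list alone). With the replicate number as a factor 34 rose and 0 fell. All 39 had a positive change, with a median log2 change of 1.34 (camera adjusted p = 2.77e-60). Among them were Acta2, smooth muscle alpha-actin, which went from 4960 ± 1177 to 20609 ± 1262 (SD, n = 3), Ccn1, a secreted matricellular protein (2754 ± 295 to 11555 ± 1017, SD, n = 3), and Cnn1, calponin, from 4.59 ± 0.04 to 37.0 ± 3.59 (SD, n = 3). Actg2, enteric smooth muscle gamma-actin, rose by 2.51 on the log2 scale, from 12.1 to 144, and binding of Acta2 transcripts to its probe set was not excluded at these intensities. Vcl, vinculin, rose by 1.33, but lost its call in limma without control replicate 1, 3 or 7 (adjusted p = 0.0605, 0.0674 and 0.0846), without cytochalasin D replicate 3 (adjusted p = 0.092) or without double-drug replicate 3 (adjusted p = 0.0529). Ccn2 rose by 2.02, Actg1, cytoplasmic gamma-actin, by 0.47 (adjusted p = 0.00174), and Actb, cytoplasmic beta-actin, had a change of 0.24 (adjusted p = 0.125), which did not pass the test.

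Overlapping lists moved with them. Of the actin and actin-turnover genes 7 of 25 rose (12 adjusted over the list alone, camera adjusted p = 8.84e-15), among them Dstn, the depolymerizing factor destrin (0.83). Of the focal adhesion genes 8 of 26 rose (13 adjusted over the list alone, adjusted p = 8.46e-21), among them Itga5, the fibronectin receptor subunit (1.93), Csrp1 (1.66) and Tgfb1i1 (1.47). Most called members of both lists are MRTF-SRF list members as well. Of the smooth muscle contractile genes 6 of 13 rose (9 adjusted over the list alone, adjusted p = 2.58e-17), and all 6 are MRTF-SRF list members as well. The genes that the study group followed up, Errfi1 (2.31), Pkp2 (2.66), Fhl1 (1.80) and Lima1 (1.87), all rose (4 adjusted over the list alone, adjusted p = 4.29e-13); a list the study chose on these samples is not independent evidence. Errfi1 encodes an inhibitor of the EGF receptor and Lima1 an actin-binding LIM protein.

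Immediate-early genes, which respond to signals without new protein, rose too: 9 of 23 rose and 14 were not called (16 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.37e-21). Zfp36, a protein that destabilizes mRNA, went from 320 ± 59.3 to 1993 ± 218 (SD, n = 3), a log2 change of 2.59. Ier2 rose by 2.13, Junb by 1.51 and Ier5 by 1.22. The fixed genes Fos and Egr1 had changes of 2.12 (adjusted p = 0.129) and 0.78 (adjusted p = 0.14), which did not pass the test. All 6 list tests given so far held with an estimated correlation (adjusted p = 0.0156 for MRTF-SRF targets, actin and smooth muscle genes, 0.0178 for focal adhesion genes, 0.0231 for the followed-up genes and 0.0444 for immediate-early genes).

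Fewer probe sets were called lower than higher, and by smaller changes, although at an unadjusted p under 0.05 more were lower (1526) than higher (1226). Arrdc3, an arrestin-domain protein, fell by 2.56 on the log2 scale, from 1454 ± 148 to 239 ± 61.1 (SD, n = 3, adjusted p = 0.0107), and lost its call without control replicate 7 (adjusted p = 0.055). Ccl2, a monocyte chemokine, fell by 1.79 (2534 ± 454 to 725 ± 141, SD, n = 3, adjusted p = 0.00862). Gadd45b, a stress-response gene, fell by 1.21, Tent5a by 1.30 and Ifnz, an interferon, by 1.25. These 4, without Arrdc3, kept their calls with any single array left out. Fam43a (−1.80), Hoxd3os1 (−1.79), the linker histone gene H1f2 (−1.33), Snai1, a repressor of epithelial genes (−1.18), and Zfp472 (−0.94) were called as well. Their calls ended without 1 array: Fam43a without control replicate 3 or 7 (adjusted p = 0.054 and 0.0561), Hoxd3os1 without cytochalasin D replicate 7 (0.0574), and Zfp472 without control replicate 3 or 7 or cytochalasin D replicate 3 (0.0691, 0.065 and 0.0504). H1f2 lost its call without any control array (0.0537, 0.0862 and 0.0855 for replicates 1, 3 and 7), cytochalasin D replicate 1 or 3 (0.0632 and 0.107) or double-drug replicate 3 (0.059). Snai1 lost it without any array other than cytochalasin D replicate 1, with adjusted p between 0.0583 and 0.14.

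Lists outside the cytoskeleton held few calls in this contrast. YAP/TAZ-TEAD targets had 4 of 23 members higher and 1 lower (4 and 2 adjusted over the list alone); the 4 were Ankrd1, Ccn1, Ccn2 and F3, of which the first 3 are MRTF-SRF list members, and the lower one was Gadd45b. Among p53 targets Pmaip1, a promoter of apoptosis (2.36), Btg2 (2.61) and Zmat3 (0.99) rose among 19 tested (6 rose and 1 fell adjusted over the list alone). Btg2, an immediate-early list member too, lost its call without control replicate 7 (adjusted p = 0.0581) or cytochalasin D replicate 3 (adjusted p = 0.0594). NF-kappaB targets had Ptgs2, cyclooxygenase 2, higher (1.40) and Ccl2 lower among 17 (1 and 3 adjusted over the list alone), and Ptgs2 was not called without control replicate 3 (adjusted p = 0.0539). Feedback inhibitors had Dusp5 higher and Dusp7 lower among 18 (1 and 3 adjusted over the list alone), and EGF family ligands had Ereg higher among 5 (2 adjusted over the list alone). Snai1 and Snai2 fell among 17 TGF-beta and BMP response genes (1 rose and 5 fell adjusted over the list alone); Snai2 (−0.65) was not called without control replicate 3 or 7 or cytochalasin D replicate 3 or 7 (adjusted p = 0.0535, 0.0736, 0.0783 and 0.0528). Single members rose among circadian clock genes (Nfil3, 1 of 16) and tubulins (Tubb6, 1 of 18; 1 and 2 rose, and 0 and 1 fell, adjusted over the list alone). Of the stress response genes Ppp1r15a (1.13) and Atf4 (0.32) rose among 19 (2 adjusted over the list alone), Ppp1r15a without a call when control replicate 3 or 7 was left out (adjusted p = 0.0514 and 0.0518). Of the heat shock genes Hspe1 fell by 0.24 among 11 (1 rose and 1 fell adjusted over the list alone); its call was lost without any array other than cytochalasin D replicate 1, with adjusted p between 0.0893 and 0.157.

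The list tests of 4 of these groups passed at the preset correlation and not with an estimated one. NF-kappaB targets were lower (adjusted p = 0.0098; adjusted p = 0.401 with an estimated correlation). EGF family ligands (0.00813; 0.308), p53 targets (0.0116; 0.0963) and extracellular matrix genes (0.0464; 0.381) were higher. These calls ended without control replicate 7 or cytochalasin D replicate 1 for NF-kappaB targets (adjusted p = 0.0793 and 0.13), without control replicate 7 for EGF ligands (0.0556), and without cytochalasin D replicate 7 for p53 targets (0.0628). The call of p53 targets also ended with the replicate number as a factor (adjusted p = 0.0635). For the extracellular matrix list the call ended without control replicate 1 or 7 (0.124 and 0.166), cytochalasin D replicate 3 or 7 (0.111 and 0.298) or double-drug replicate 3 (0.053). The other list tests did not pass, the smallest adjusted p being 0.0613 for TGF-beta and BMP response genes. Of these, 3 passed without 1 array: the TGF-beta list without control replicate 7 (0.0288), G2/M genes without cytochalasin D replicate 1 (0.00312), and G1/S genes without control replicate 3 or cytochalasin D replicate 1 (0.00745 and 0.0082). With all arrays and an estimated correlation, camera gave these 3 lists adjusted p = 0.324, 0.862 and 0.839. Extracellular matrix, G2/M, G1/S and cholesterol synthesis genes held 0 calls in limma among 25, 19, 20 and 15 members, also adjusted over the list alone. The median change and the direction of the test differed in sign for YAP/TAZ-TEAD targets, stress response, heat shock, circadian clock and tubulin genes, none of whose list tests passed. For feedback inhibitors, cholesterol synthesis genes and skeletal muscle markers, whose tests did not pass either, the mean and the median or the test differed in sign.

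The second contrast asks what changed when latrunculin B was present with cytochalasin D. Immediate-early genes and a few cytoskeletal genes were higher than in controls, though for Srf, Fosl1 and Csrp1 1 of 2 probe sets was called, for Ccn1 1 of 4 and for Atf4 1 of 3. Srf rose to 827 ± 164 (SD, n = 3), a log2 change of 2.05 (SE 0.21, adjusted p = 0.0393). Zfp36 rose to 1327 ± 155 (SD, n = 3), a change of 2.01 (adjusted p = 0.0172), and Ier2 to 4068 ± 526 (SD, n = 3), a change of 1.73 (adjusted p = 0.0172). Ccn1 rose by 1.70, Dusp5 by 1.52, Fosl1, a partner of Jun proteins, by 1.22, Tubb6, a beta-tubulin, by 1.12, Mob3a by 1.04, Junb by 0.99 and Csrp1 by 0.84. Ifnz fell by 1.30 (adjusted p = 0.0384), about as in the first contrast. Acta1, the largest rise with cytochalasin D, had 56.0 ± 18.3 (SD, n = 3) here, a change of 1.0 (adjusted p = 0.619), and Acta2 one of 1.02 (adjusted p = 0.167), neither of which passed the test.

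Here 30 probe sets were called, 27 higher and 3 lower, for 25 and 3 genes, 14 and 1 of them with at least a 2-fold change. Among all probe sets tested 8.08% had group values that did not overlap, where chance gives 10%, so this share showed no excess. The count was 123 with the pairs, 85 higher and 38 lower, of which 24 were among the 30. It rested on single arrays: it was 1 without control replicate 3, 2 without control replicate 7, 1 without cytochalasin D replicate 1, 2 without cytochalasin D replicate 3 and 16 without cytochalasin D replicate 7. It was 1, 0 and 0 without double-drug replicates 1, 3 and 7 (limma, with 1272, 1242 and 1206 probe sets at an unadjusted p under 0.05), and 42 without control replicate 1. None of the 14 calls of named genes held with every single array left out, the adjusted p reaching 0.218 at most. The 30 probe sets kept their direction each time, but their group values did not overlap, so this was fixed in advance. Dusp5 and Csrp1 were not called with the pairs (adjusted p = 0.0623 and 0.0744), whereas Lima1 (1.04, adjusted p = 0.0754) and Errfi1 (1.21, adjusted p = 0.112) were called with them (adjusted p = 0.00859 and 0.0106). Also called with the pairs alone were Fam126b (1.47, adjusted p = 0.0844, and 0.0288 with the pairs), Gcnt2 (0.79, 0.0754 and 0.0481), Tgfb1i1 (0.84, 0.101 and 0.0383), Pdlim7, a LIM protein of stress fibres (1.16, 0.16 and 0.0296), and Ptgs2 (0.99, 0.14 and 0.0293). Lower with the pairs alone were H1f2 (−0.84, adjusted p = 0.326, and 0.00571 with the pairs), Tent5a (−0.96, 0.0976 and 0.0269) and Gadd45b (−0.86, 0.118 and 0.0291).

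Among the lists, 5 of 39 MRTF-SRF targets rose and 34 were not called (22 rose adjusted over the list alone); the 5 were Srf, Ccn1, Csrp1, Tpm4, a tropomyosin (0.59), and Actg1 (0.41). The list had a median log2 change of 0.55 (camera adjusted p = 2.79e-34, and 0.0231 with an estimated correlation). Of the immediate-early genes 4 of 23 rose (15 adjusted over the list alone, 7 with the pairs), with a median change of 1.06 (adjusted p = 3.37e-21, and 0.0444 with an estimated correlation). The actin list had 1 riser among 25 (Actg1; 8 adjusted over the list alone, 2 with the pairs) and the focal adhesion list 1 among 26 (Csrp1; 8 adjusted over the list alone, 2 with the pairs). Both tests passed (adjusted p = 1.73e-09 and 1.2e-12) and held with an estimated correlation (adjusted p = 0.0178 and 0.0444). The smooth muscle list (0 of 13 called, 3 adjusted over the list alone) and the followed-up genes (0 of 4 called, 3 adjusted over the list alone, 2 with the pairs) passed as lists (adjusted p = 1.26e-05 and 5.15e-06) but not with an estimated correlation (adjusted p = 0.0963 for each). The followed-up genes were chosen by the study on these samples and are not independent evidence.

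Of the other lists in this contrast, YAP/TAZ-TEAD targets (Ccn1), feedback inhibitors (Dusp5), stress response genes (Atf4, 0.25) and tubulins (Tubb6) had 1 riser each among 23, 18, 19 and 18 members. Adjusted over the list alone these lists had 3, 1, 4 and 1 risers and 2, 1, 0 and 0 fallers, and with the pairs the feedback list had none and the YAP/TAZ-TEAD list 1 faller besides. The remaining lists outside the cell type markers held 0 calls in limma over all probe sets, of which 1425 had an unadjusted p under 0.05. Adjusted over the list alone, p53 targets had 2 risers, NF-kappaB targets 1 riser and 1 faller (as with the pairs), TGF-beta and BMP response genes 1 faller, and EGF ligands and circadian clock genes 1 riser each. Higher as lists were cholesterol synthesis genes (adjusted p = 0.00288; 0.249 with an estimated correlation), stress response genes (0.00321; 0.293) and p53 targets (0.032; 0.138). Lower were NF-kappaB targets (0.00697; 0.381) and TGF-beta and BMP response genes (0.00907; 0.181). With the pairs the tests of p53 targets and the TGF-beta list did not pass (adjusted p = 0.142 and 0.0599). Single arrays ended the call of p53 targets (adjusted p = 0.112 without control replicate 3, 0.0516 and 0.0776 without cytochalasin D replicates 1 and 7, and 0.0855 without double-drug replicate 1). They also ended those of NF-kappaB targets (0.226 without control replicate 7 and 0.0855 without double-drug replicate 1) and of the TGF-beta list (0.0619 without double-drug replicate 3). Lists that passed only without 1 array were EGF ligands and heat shock genes (without control replicate 1, adjusted p = 0.00635 and 0.0292), G1/S genes (0.00982 without control replicate 3, 0.019 without double-drug replicate 1) and G2/M genes (0.00567 without double-drug replicate 1). With all arrays and an estimated correlation, camera gave them adjusted p = 0.582, 0.582, 0.855 and 0.862. For YAP/TAZ-TEAD targets and tubulins the median and the test differed in sign, and for adipocyte markers the mean and the test did; none of these tests passed.

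Both contrasts use the same 3 controls. All 27 probe sets called higher in the double-drug group were also called higher with cytochalasin D, and the 3 called lower were also called lower. Independent lists of these sizes would share 0.309 and 0.0127 probe sets, and 20 simulations with no effect and shared controls gave 0. Across probe sets, which are not independent replicates, the 2 sets of log2 changes correlated at 0.784 (0.501 in the simulations), with a covariance of 0.0308 (0.0114 in the simulations, a difference of 0.0194). The simulated values hold the shared controls but no effects, so shared calls near 0 were fixed in advance, and the independent lists hold neither. The controls are too few to split, so part of the excess of shared calls may come from sharing them; the difference in covariance leaves their share out. Of the 309 probe sets that rose with cytochalasin D, 298 had a smaller change in the double-drug group. The 309 were chosen by their rise with cytochalasin D, so smaller changes in the other group would be common without any effect of latrunculin B. By the direct test, 65 of the 309 were lower in the double-drug group. The plot of both changes against each other shows the MRTF-SRF targets and immediate-early genes among the probe sets tested.

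**Figure D2:**
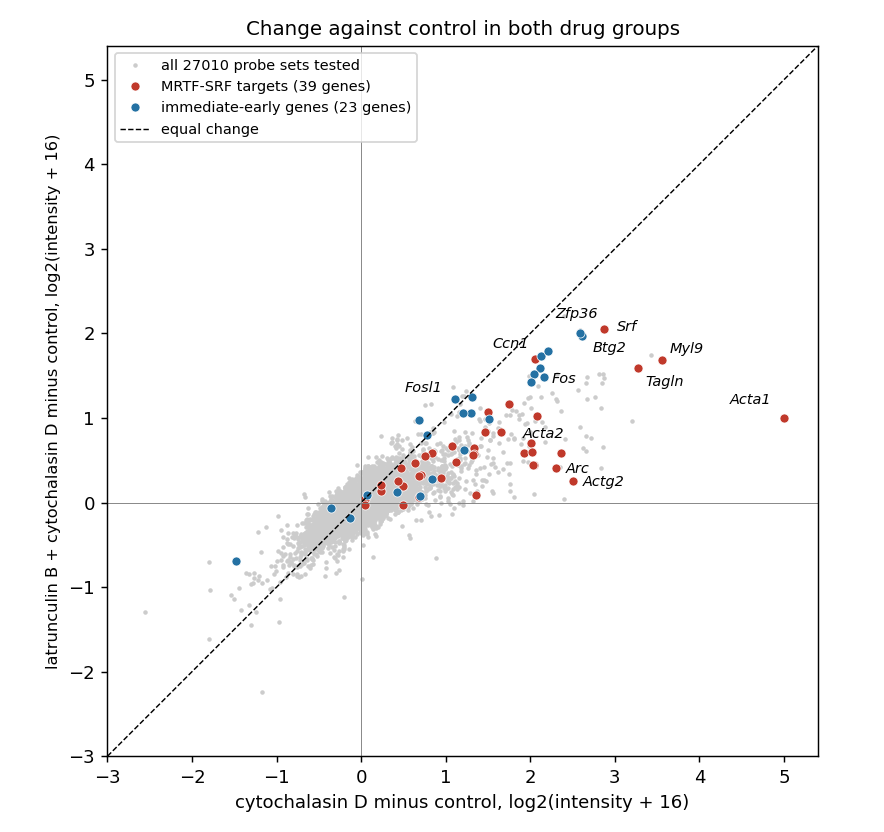
Log2 change against control with cytochalasin D (x axis) and with latrunculin B and cytochalasin D (y axis) of 27010 probe sets (grey), with 39 MRTF-SRF targets (red) and 23 immediate-early genes (blue), 1 probe set per gene; the dashed line marks equal change. Acta1 lies at 5.00 and 1.0, Zfp36 at 2.59 and 2.01; the changes share their controls.

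The third contrast sets the drug groups against each other and tests directly where the added latrunculin B made a difference. Some cytoskeletal genes were higher with cytochalasin D alone, while others did not pass the test. Binding of Acta2 transcripts to the probe sets of Acta1 and Actg2 was again not excluded. Acta1 differed by a log2 change of 4.0 (1168 ± 479 against 56.0 ± 18.3, SD, n = 3, adjusted p = 0.0113). Actg2 differed by 2.24 (144 ± 17.3 against 17.9 ± 4.71, SD, n = 3, adjusted p = 0.00727) and Pkp2 by 2.05 (870 ± 160 against 201 ± 59.2, SD, n = 3, adjusted p = 0.0371). The next were Lurap1l (1.94), Arc, a synaptic immediate-early gene (1.90), Gcnt2, a glycosyltransferase (1.87), Ankrd1, a nuclear ankyrin-repeat protein of muscle (1.77), Fhl1, a LIM protein (1.74), Tuft1 (1.61) and Gadd45g (1.54, 7737 ± 778 against 2649 ± 333, SD, n = 3). Of several probe sets of a gene, 2 of 3 were called for Pkp2 and Lurap1l, 1 of 6 for Gcnt2, 1 of 4 for Itga5 and 1 of 2 for Socs5. Gadd45g was not called against control in either drug group (changes of 0.89 and −0.66, adjusted p = 0.0811 and 0.492). Lower with cytochalasin D alone were Socs5, a suppressor of cytokine signalling (−0.33, adjusted p = 0.0336), and Zfp979 (−0.22, adjusted p = 0.0463). Srf (0.82, adjusted p = 0.504), Tagln (1.68, adjusted p = 0.319), Vcl (0.69, adjusted p = 0.554), Acta2 (1.06, adjusted p = 0.147) and Zfp36 (0.58, adjusted p = 0.472) did not pass the test. Acta2 passed without control replicate 7 (adjusted p = 0.0364) and 2 dimmer probe sets of it were called, and Zfp36 passed with the pairs (adjusted p = 0.035).

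The test called 70 probe sets, 67 higher and 3 lower with cytochalasin D alone, for 54 and 3 genes, and 41 of the higher ones changed at least 2-fold. Among all probe sets tested 6.26% had group values that did not overlap, where chance gives 10%, so this share showed no excess. With the pairs the test called 99, of which 41 were among the 70. Without single arrays the count was 11 and 31 (control replicates 3 and 7), 31, 23 and 26 (cytochalasin D replicates 1, 3 and 7) and 5, 3 and 4 (double-drug replicates 1, 3 and 7). Of the 20 called results of named genes, those of Cnn1 (1.27, adjusted p = 0.000913), Actg2 and Gcnt2 held with each single array left out. In controls Cnn1 lay under the 40th percentile of the arrays (6.16 to 6.27), and its change in the double-drug group was 0.09. Actg2 was near the floor too (12.45 to 21.07 in the double-drug group), and binding of Acta2 transcripts was not excluded for it. The spread of values near the floor is small, which favours such calls. Not all probe sets of Gcnt2 were called. Acta1 lost its call without control replicate 3 (adjusted p = 0.0515) or double-drug replicate 1, 3 or 7 (adjusted p = 0.0599, 0.0649 and 0.0694), and the 16 others without 5 or more of the arrays, with adjusted p up to 0.208. With the pairs Ankrd1 (adjusted p = 0.0635), Tuft1 (0.0631), Zfp979 (0.0896), Ccn2 (1.42, 0.0377 without the pairs and 0.086 with them), Itga5 (1.34, 0.031 and 0.058), Csrp1 (0.83, 0.0342 and 0.0831), Dusp5 (1.33, 0.0384 and 0.0871) and Dstn (0.40, 0.0488 and 0.0831) were not called. Called with the pairs alone were Fam126b (1.41, adjusted p = 0.0805, and 0.035 with the pairs) and Mob3a (0.72, 0.0981 and 0.0455), higher, and H1f2 (−0.49, 1 and 0.0271) and the clock gene Bhlhe40 (−0.74, 1 and 0.0413), lower.

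The switch set, called in the same direction against control and against the double-drug group, held 65 probe sets that were highest with cytochalasin D alone and 3 that were lowest, for 52 and 3 genes, and 40 of the 65 differed at least 2-fold in both contrasts. With the pairs 83 were highest and 12 lowest, and 37 of the 65 were among the 83. Among its largest members were Acta1, Actg2, Pkp2, Lurap1l, Arc, Gcnt2, Ankrd1, Fhl1, Tuft1 and Rassf6, a Ras-association protein with 11 ± 2.94 in controls, 77.0 ± 24.2 with cytochalasin D and 15.4 ± 0.86 in the double-drug group (SD, n = 3). Socs5 and Zfp979 were among the 3 lowest. Both contrasts share the cytochalasin D arrays. Simulations with no effect gave 0 switch probe sets, and independent lists of these sizes would share 0.766 of the higher ones. The simulated noise held no effects and no structure by replicate number, so calls near 0 were fixed in advance. The independent lists leave out the shared arrays. Neither value shows what shared arrays or such structure yield here. Of the 27 probe sets higher in both drug groups than in controls, 8 were higher with cytochalasin D alone by the direct test. Like the contrast it rests on, the set shrank without single arrays: to 11 and 30 (control replicates 3 and 7), 30, 23 and 25 (cytochalasin D replicates 1, 3 and 7) and 5, 3 and 4 (double-drug replicates 1, 3 and 7).

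By list, 10 of 39 MRTF-SRF targets were higher with cytochalasin D alone and 29 were not called (28 adjusted over the list alone, 4 with the pairs), with a median log2 difference of 0.64 (camera adjusted p = 8.96e-56, and 0.0156 with an estimated correlation). Smooth muscle genes (2 of 13, 9 adjusted over the list alone, adjusted p = 1.9e-20), focal adhesion genes (2 of 26, 7 adjusted over the list alone, 0 with the pairs, adjusted p = 1.45e-16) and actin genes (3 of 25, 6 adjusted over the list alone, adjusted p = 5.85e-11) were higher too. Their tests held with an estimated correlation (adjusted p = 0.0156, 0.0245 and 0.0156). Apart from Dstn, the called members of these lists are MRTF-SRF list members as well, so they are not separate evidence. The followed-up genes had Pkp2 and Fhl1 called among 4 (4 adjusted over the list alone, 4 with the pairs, adjusted p = 1.42e-15, and 0.0178 with an estimated correlation), and this list is not independent evidence, since the study chose it on these samples. Lima1 and Errfi1 were the members called with the pairs alone (0.83 and 1.11, adjusted p = 0.126 and 0.136, and 0.0234 and 0.0175 with the pairs). Immediate-early genes had 0 of 23 called in limma (4 adjusted over the list alone, 1 with the pairs) and a median difference of 0.40, and the list test passed (adjusted p = 6.65e-07) but not with an estimated correlation (adjusted p = 0.262).

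Further lists were higher with cytochalasin D alone at the preset correlation and not with an estimated one. These were extracellular matrix genes (adjusted p = 0.00205; 0.181 with an estimated correlation), YAP/TAZ-TEAD targets (0.00321; 0.115), EGF ligands (0.00502; 0.287) and p53 targets (0.0495; 0.171), the last with a median difference just under 0. Cholesterol synthesis genes were lower (0.0225; 0.381). The YAP/TAZ-TEAD list had 2 of 23 members called, Ankrd1 and Ccn2 (3 adjusted over the list alone, 1 with the pairs). The feedback list had 1 of 18 (Dusp5, 1 adjusted over the list alone, 0 with the pairs), and the circadian clock list had 1 of 16 (Nfil3, 0.82, 1 adjusted over the list alone, and 1 faller besides with the pairs). Adjusted over the list alone 2 EGF ligands and 2 p53 targets were higher, and 3 stress response and 2 cholesterol synthesis genes lower. Over all probe sets, of which 1141 had an unadjusted p under 0.05, limma called none of these. With the pairs, Ereg (1.08, adjusted p = 0.0413) was called. With the pairs the tests of p53 targets and cholesterol synthesis genes did not pass at the preset correlation (adjusted p = 0.0506 and 0.0531) and that of G1/S genes did (0.0429, and 0.422 without the pairs). Single arrays ended the calls of p53 targets (adjusted p = 0.0527 without control replicate 3, 0.0575, 0.123 and 0.248 without cytochalasin D replicates 1, 3 and 7, and 0.0619 and 0.127 without double-drug replicates 3 and 7). They also ended those of cholesterol synthesis genes (0.727 without cytochalasin D replicate 1, 0.0619 and 0.0806 without double-drug replicates 3 and 7) and, without cytochalasin D replicate 7, of YAP/TAZ-TEAD targets (0.124) and the extracellular matrix list (0.0888). Lists that passed without 1 array were G2/M genes (without cytochalasin D replicate 1, adjusted p = 0.00314, and in the opposite direction without replicate 3, 0.0274), G1/S genes (0.0256 without cytochalasin D replicate 1, 0.0275 without double-drug replicate 3) and stress response genes (0.00513 without cytochalasin D replicate 1). With all arrays and an estimated correlation, camera gave these lists adjusted p = 0.984, 0.862 and 0.812. The other lists did not pass, and the median and the test differed in sign for circadian clock, tubulin and fibroblast lists.

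The bar plot of gene lists gives the shares called in the 3 contrasts.

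**Figure D3:**
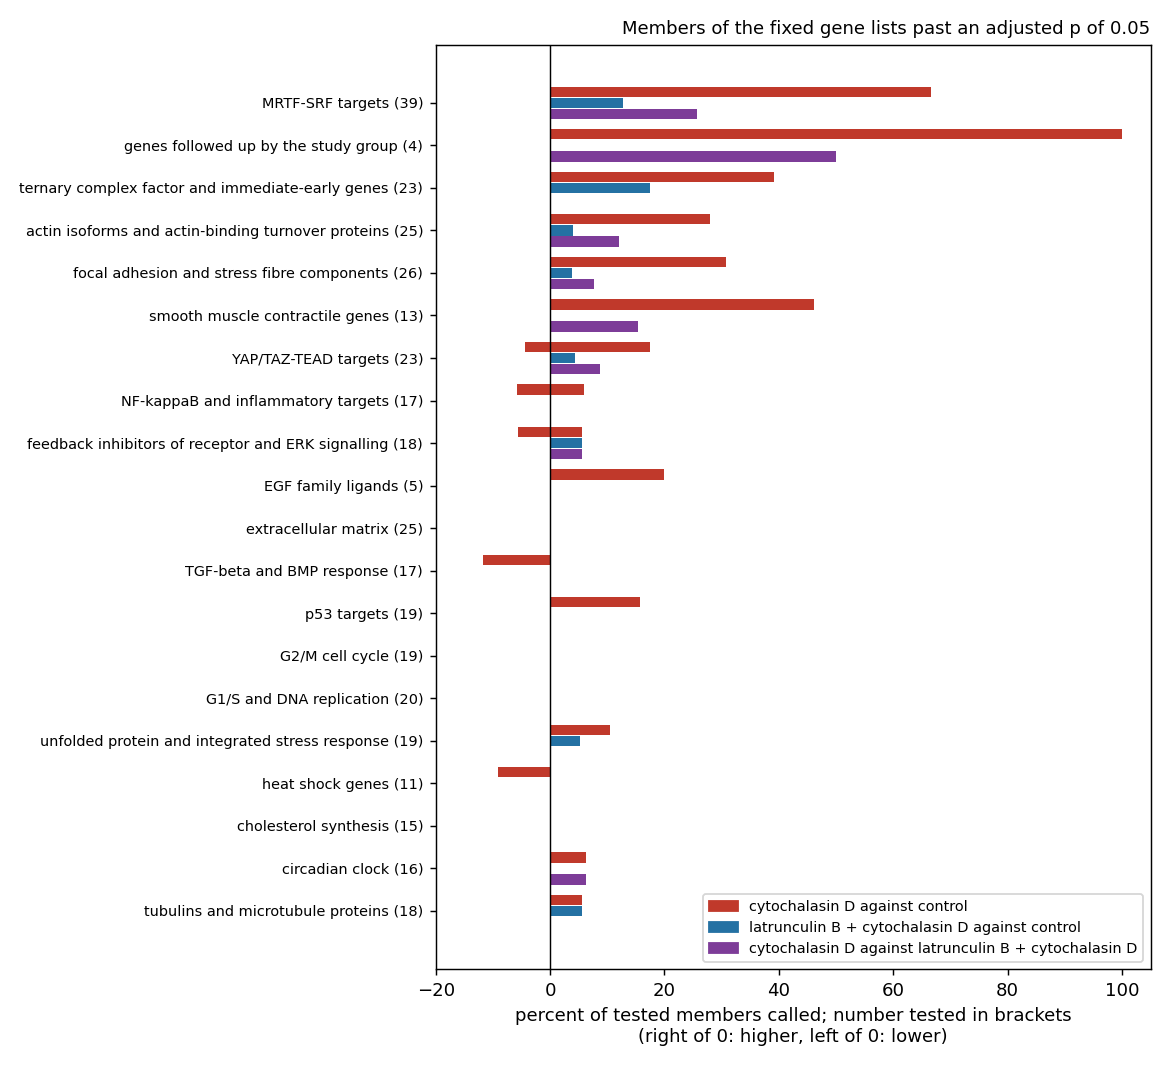
Percent of tested members called at an adjusted p under 0.05 (x axis; right of 0 higher, left of 0 lower) for 20 lists, without those of cell type markers, in the 3 contrasts (colours); numbers of tested members are in brackets. Of the 39 MRTF-SRF targets, 26 were higher with cytochalasin D than in controls, 5 in the double-drug group than in controls, and 10 with cytochalasin D than in the double-drug group.

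Markers of cell types held 0 calls in limma in the 3 contrasts, over all probe sets and adjusted over the list alone (2752, 1425 and 1141 probe sets of any kind had an unadjusted p under 0.05). Tested were 12 fibroblast, 6 macrophage and leukocyte, 4 epithelial, 2 endothelial, 4 adipocyte and 7 skeletal muscle markers, and no list test passed, the smallest adjusted p being 0.364. Skeletal muscle markers had a median log2 change of 0.001 with cytochalasin D (adjusted p = 0.921), while Acta1 rose. The difference between 3′ and 5′ control probe sets of Actb, a measure of RNA integrity, was 0.94 ± 0.20 in controls, 0.62 ± 0.11 with cytochalasin D and 0.79 ± 0.13 in the double-drug group (log2, SD, n = 3). Exact permutation tests gave p = 0.2 for cytochalasin D against control, p = 0.3 for the double-drug group against control and p = 0.3 between the drug groups, two-sided, with 0.1 the smallest p that 3 against 3 arrays allow. Within each replicate number the difference was lowest with cytochalasin D and highest in controls (0.56, 0.69 and 0.72 for cytochalasin D, the double-drug group and control at number 1; 0.56, 0.74 and 1.05 at number 3; 0.74, 0.93 and 1.07 at number 7). Exact paired permutation tests of the contrasts the numbers pair, chosen after these values were seen, gave p = 0.25 each, the smallest that 3 pairs allow. The 3′ to 5′ difference for Gapdh was −0.32 ± 0.05, −0.31 ± 0.05 and −0.33 ± 0.03 (log2, SD, n = 3), without the order seen for Actb. Actb is itself an MRTF-SRF list member, and its control probe sets were brighter on the drug arrays than in controls. Its difference may therefore not measure RNA integrity alone.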

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

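The rule by which these values stand out was chosen only after the result was seen, and no explanation was tested. Control probe sets, which enter none of the contrasts, stand out where an array with a drug lies over the highest control array by more than the range of the control arrays. The hybridisation spike-ins, bacterial transcripts added in fixed amounts before hybridisation, had a mean log2 intensity of 11.01 on double-drug replicate 1, where the control arrays had 9.07 to 9.47. The Actb control probe sets had mean log2 intensities of 14.36, 14.49 and 14.27 on cytochalasin D replicates 1, 3 and 7, where the control arrays had 13.70 to 13.98. The double-drug arrays, with 14.17, 14.24 and 14.07, lay over the control arrays too, but by less than their range. Poly-A spike-ins had 8.92 to 9.06 on the control arrays, 8.64 and 8.25 on cytochalasin D replicates 3 and 7, and 8.63 and 8.2 on double-drug replicates 3 and 7, but 8.90 and 9.07 on replicate 1 of these groups. The probe set of Actb used among the tested genes had a change of 0.24 with cytochalasin D that did not pass the test.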

How the results depend on the processing

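Leaving out all 3 arrays of a replicate number was chosen only after the result was seen; the other alternatives were chosen before. Cytochalasin D against control (423 probe sets) gave 1044 with the replicate block (626 higher, 418 lower, 400 of them among the 423), 159 with only the 6 arrays compared, 183 at least 2-fold and 275 with 1 probe set per gene. Correlations of same-numbered arrays were 0.71, 0.076 and 0.653 here, number 3 lying under the cut of 0.1, although each array correlated best with its own number. The numbers pair the double-drug arrays with those of both other groups, so they may pair this contrast too. With the block, at the preset correlation, the p53 list lost its call (adjusted p = 0.0635) and the G1/S list passed (0.00772), with 2 members called lower. Of the extracellular matrix genes 2 were called higher. The double-drug group against control (30) gave 123 with the replicate block, 74 with the filter at the 60th percentile, 15 with quantile normalization, 15 at least 2-fold, 14 with pseudocount 64, 12 after median centring, 8 without a filter and 1 with only the 6 arrays compared. Cytochalasin D against the double-drug group (70) gave 44 with 1 probe set per gene, 41 at least 2-fold, 16 without a filter and 9 with only the 6 arrays compared. The switch set (68) gave 42, 40 and 16 with 1 probe set per gene, at least 2-fold and without a filter. With arrays left out the counts ran from 0 to 478, 0 to 42, 0 to 59 and 0 to 59, in that order. Without the number 3 arrays all 4 were 0 (limma, 1551, 1027 and 719 probe sets at an unadjusted p under 0.05 in the 3 contrasts). Without the number 7 arrays they were 19, 1, 0 and 0 (1292 at an unadjusted p under 0.05 between the drug groups), and without the number 1 arrays 302, 0, 6 and 6 (1896 for the double-drug group against control). The double-drug group against control also gave 0 without double-drug replicate 3 or 7 (1242 and 1206). Fewer arrays, genes or probe sets enter by construction in the leave-outs, the 6-array fits and the 1-per-gene fit, and more probe sets are adjusted without a filter; otherwise the cause was not tested.

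In every alternative the called probe sets that were tested kept their direction. Their group values did not overlap, so leaving out arrays could not reverse them, and this is no sign of stability. Of 60 called named-gene results of cytochalasin D against control, 45 kept their call in the processing alternatives run for genes (the 2-fold and 1-per-gene ones were run for counts) and 46 in all single-array leave-outs, against 0 and 0 of 14 for the double-drug group against control and 1 and 3 of 20 for the third contrast. With the replicate numbers left out as well, 0 of the 94 called results kept their call throughout. Of the 32 list tests called, 15 kept their call in every alternative run for lists (not the 6-array, 2-fold and 1-per-gene ones). The G2/M list, uncalled between the drug groups, reversed to higher with cytochalasin D alone without cytochalasin D replicate 3 (adjusted p = 0.0274), its adjusted p running from 0.00314 to 0.987 over single arrays left out. In the contrasts the numbers pair, the block changed the calls given with the results and no other call of a list or gene named there.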

Other observations

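The tests of the number 1 arrays, of the larger kept share itself, of the actin probe sets and of the splits within replicate numbers were chosen only after the result was seen. The other splits were chosen before the data were examined, and the tests of brightness and size of rise after the pattern but before their own results were seen. On the first principal component (46.6% of the variance) the arrays numbered 1 had the lowest value in all 3 groups. With cytochalasin D they were not set apart there, since number 3 lay between (−32, −14.5 and 10.1 for numbers 1, 3 and 7). The arrays numbered 1 stood apart by limma with group in the model. It called 3457 probe sets for number 1 against the other numbers (1745 higher, 1712 lower), 25 for number 7 and 0 for number 3. Mitotic genes were higher on the number 1 arrays: Kif11, a spindle motor, had 293 on control replicate 1 and a mean of 149 on the other control arrays, 326 and 160 with cytochalasin D, and 314 and 156 in the double-drug group. Ube2c, Birc5 and Kif20a had mean log2 differences of 0.82, 0.77 and 0.76, and Ccnb2 one of 0.07, all genes chosen after their values were seen.

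Strength of hybridisation or scanning of the number 1 arrays is argued against as the whole cause: the median difference of the G2/M list, 0.45, lay at percentile 100 of 10000 lists matched on mean expression (central range −0.16 to 0.10), which ignores correlation between genes. Hybridisation spike-ins were highest on number 1 in both drug groups (9.78 against 9.14 and 9.03 with cytochalasin D, 11.01 against 9.24 and 9.46 in the double-drug group) but not in controls (9.42 against 9.07 and 9.47), so a part of it stays open. More cycling cells in the number 1 cultures may explain part of it, since 23 of 39 G2/M and G1/S members (59%) were highest on number 1 in all 3 groups, against 14.2% of all genes. The labels do not say what the numbers mark, so a batch, a day or a state of the culture stays open, and the design gives no biological group to set against them.

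Immediate-early genes called with cytochalasin D kept a median of 74.5% of their log2 rise in the double-drug group (9 genes), and MRTF-SRF targets 44.7% (26 genes), a difference of 29.8 percentage points (permutation p = 0.0033). Other called genes kept 46.4% (138 genes), about as MRTF-SRF targets did, so the immediate-early genes were those with the higher share. With only members over an intensity of 1000, the difference was 25.9 points (permutation p = 0.0081). This cut kept all 9 immediate-early genes and 20 of the 26 MRTF-SRF targets. It did not match the sets on brightness, so it cannot decide whether brighter genes kept a larger share. A larger kept share of genes with smaller rises as the whole cause is argued against by the residual from the trend over other called genes, 0.648 log2 (permutation p = 0.0029). A hypothesis is that latrunculin B may hold back MRTF-SRF targets more than immediate-early genes. By the agent labels no group had latrunculin B alone, so a kept rise cannot be told apart from a rise that latrunculin B itself made. Genes of a list are not independent, and the shares come from the same 9 arrays in which the pattern was seen.

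Transcripts of Acta2 could bind the probe sets of its close relatives Acta1 and Actg2. If they made all of the rise, in proportion to the bright Acta2 probe set (at least 3634 in controls), control arrays would have read at least 174 for Acta1 and 25.4 for Actg2, where they averaged 19.2 and 12.1. The shortfall was 155 or more for Acta1 and 13.4 or more for Actg2, and a dim Acta2 probe set fell short in the same way by up to 37.3. As a ratio of needed to read, Acta1 had 9.05 or more and Actg2 2.11 or more, and that Acta2 probe set up to 9.36. So for both genes their own rise and binding of Acta2 transcripts cannot be told apart, because an Acta2 probe set near the floor of the values departed from the bright one as far in ratio.

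Other splits of the arrays were fitted in limma. For each contrast the real split was the 1 of 10 that called most: 423, 30 and 70 probe sets, where the highest other split called 0, 1 and 0. At an unadjusted p under 0.05 the real split was not the largest in any contrast. It had 2752, 1425 and 1141 probe sets, where the highest other split had 4889, 2872 and 4063. With 10 splits a share under 0.05 cannot be reached. Among splits that part all 3 pairs, the others called 0 in the 2 paired contrasts. For the switch set, 3 of 100 splits drawn from 840 gave 68 or more, the real one included, and the 2 others, with up to 843, set the 3 number 1 arrays apart and point to a structure of the samples. These splits ignore the pairing. Of the 108 splits that put 1 array of each number in each group, the real one gave most (68). The highest other, with 30, was that of the same groups with the controls set apart. These splits reshuffle all 3 groups at once, so they argue only against no difference among the groups at all. They do not exclude chance in the difference between the drug groups, for which the 10 splits cannot reach a share under 0.05. With the numbers as a block the split with the controls set apart gave 114 and the real one 95. The block kept 37 of the 65 higher switch probe sets among its 83, beside 12 lower.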
